A study of Mus musculus with 11 samples.

How the data were processed

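Expression was measured on Affymetrix MoGene 2.0 ST arrays, 1-colour whole-transcript mouse arrays hybridised with biotin-labelled material, in 11 samples of sorted mouse liver cells. The labels put 3 samples in YFP+ CDE, 3 in YFP+ DDC, 2 in YFP+ UTR (untreated) and 3 in YFP- (also untreated). Per the labels' protocols, livers were perfused with EGTA and then collagenase, undigested tissue was digested again with collagenase and pronase, and the non-parenchymal pellet was sorted on YFP, with animals lacking the label used to set the gate and a viability stain used to leave out dead cells. RNA from sorted cells was extracted with a micro-scale column kit.

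The values used are the log2 expression values that the authors deposited, 1 value per feature and array. The base of the logarithm, the background correction, the normalization and the summary of probes into features are not given in the sources used here. Base 2 was taken from the range of the values (2.55 to 13.57 over all arrays) and stays an inference, so every log2 difference and fold below rests on it. Medians of the 11 arrays ran from 5.63 to 5.76, and no pair of arrays was identical. No further normalization was applied for the main results. A feature is named by a gene number, and 23185 of the 25206 features had exactly 1 gene symbol in the platform annotation, 0 had several and 2021 were not listed and are unnamed here. Each symbol had 1 feature, so 23185 genes were tested. All 23185 matched a gene of the RefSeq table of assembly GRCm38.p6 by gene number, which was used for names only, and no coordinates are given because no build is named for the array values. Some genes of the fixed lists are not reported here.

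Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes without trend), all 11 arrays and 4 groups in 1 fit with 7 residual degrees of freedom. The 5 contrasts were YFP+ UTR minus YFP-, the unweighted mean of the 3 YFP+ groups minus YFP-, CDE minus UTR, DDC minus UTR, and DDC minus CDE. Tests were two-sided, p-values were adjusted over all genes by Benjamini-Hochberg, and the threshold was an adjusted p of 0.05. Errors are SE of the fit for differences and SD for group means. The number of arrays limits the precision. The labels do not say that the arrays of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

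The following 25 gene lists were fixed: biliary epithelium, liver progenitor and ductular reaction, hepatocyte, macrophage and Kupffer cell, neutrophil and monocyte, dendritic cell, lymphocyte, sinusoidal endothelium, stellate cell and fibroblast, erythroid and platelet, cell cycle, Notch pathway, Wnt pathway, YAP targets, inflammatory cytokines and NF-kB, extracellular matrix and fibrogenic signals, interferon response, antigen presentation by MHC class II, NRF2 and heme metabolism, cholesterol and lipid synthesis, unfolded protein and integrated stress response, immediate early and dissociation response, mesenchymal transition, p53 and senescence, and primary cilium and cyst genes. Of 479 listed symbols 446 were measured. Each list was compared with all other genes by camera on the values of the moderated t-statistics, with a preset correlation of 0.01, adjusted over the 25 lists. It was tested again by camera with a correlation estimated from the data, and by fry. The directional p of fry asks only whether the members move one way on balance. Members past the threshold were counted after adjustment over all genes and after adjustment over the list alone.

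The groups, the lists, the contrasts, the tests, the threshold and the rule for named genes were set before the data were examined. That rule takes, for each comparison, the 6 largest rises and 6 largest falls past the threshold whose arrays do not overlap between the groups (leaving out predicted genes, small RNAs and receptor segments), up to 4 members of each described list past the threshold or up to 2 where none passes, and a fixed set of marker genes. For the comparison of the diets it also takes every gene it named for either diet. A fit of the 8 YFP+ arrays alone (5 residual degrees of freedom) was chosen after the YFP- arrays had been seen to vary far more among themselves. It was used beside the 11-array result for the 3 comparisons among YFP+ groups, with the same rule for named genes. Lists of circadian clock genes and of BMP and SMAD response genes were also chosen after their values were seen.

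The fit was tested on simulated data for the same 23185 genes with 200 changed genes per comparison. Each gene was given 1 spread for all arrays, although the real YFP- arrays varied more than the YFP+ arrays. The shares from 11 arrays therefore do not measure recovery at the real spread of each group. With all 11 arrays, genes changed by 1 log2 unit were recovered in 44% of cases for UTR against YFP-, 62% for YFP+ against YFP-, 48% for CDE against UTR, 50% for DDC against UTR and 49% for DDC against CDE. For genes changed by 2 log2 units the shares were 81%, 91%, 81%, 82% and 83%. In the 8 YFP+ arrays the shares for the 3 comparisons among YFP+ groups were 63%, 61% and 76% at 1 log2 unit, and 92%, 91% and 95% at 2 log2 units. Alternatives were an intensity trend with a robust prior, a filter on dim genes, all features, a further quantile normalization, median centring, array weights, the replicate number as a block, only the groups compared, a 2-fold threshold, and leaving out each array in turn.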

Results

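The series profiled liver cells in which YFP, a yellow fluorescent protein, served as a lineage label of the biliary epithelium, and asked what becomes of these cells when the liver is injured. YFP+ cells came from mice on a choline-deficient, ethionine-supplemented diet (CDE), from mice on a diet with 3,5-diethoxycarbonyl-1,4-dihydrocollidine (DDC, 5 weeks) and from untreated mice (UTR). CDE is a model of steatotic hepatocyte injury and DDC a model of cholestatic injury, and both provoke a ductular reaction, the expansion of bile duct-like cells. YFP- cells of untreated mice were the other sorted fraction. There were 3 arrays each for CDE, DDC and YFP-, and 2 for UTR.

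The YFP+ arrays resembled each other closely, with correlations across genes of 0.98 to 0.991 between arrays, against 0.805 to 0.901 between a YFP+ and a YFP- array. The 3 YFP- arrays differed more among themselves (0.888 to 0.925), and the median SD of a gene was 0.26 in YFP-, against 0.12 in CDE, 0.15 in DDC and 0.10 in UTR (log2). The YFP- arrays also differed in kind. Replicate 1 carried transcripts of bile duct cells, with Krt19 at 8.28 against 4.64 and 4.65 in replicates 2 and 3. Replicate 2 carried lymphocyte transcripts, with the mean of the lymphocyte list 5.72 above untreated YFP+ cells against 0.53 and 1.10 on replicates 1 and 3, and had the highest levels of the myeloid genes S100a8 (12.33) and Ly6c2 (12.22), and replicate 3 the highest level of the macrophage gene Adgre1 (11.65).

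Untreated YFP+ cells were compared with YFP- cells to show what the label selects. YFP+ cells carried a bile duct profile. The transcription factor Sox9 was higher by 5.25 ± 0.72 (SE, adjusted p = 0.00115, limma), with means of 11.40 ± 0.07 (SD, n = 2) and 6.15 ± 1.66 (SD, n = 3), and the cytokeratins Krt19 and Krt7 were higher by 4.70 ± 0.91 and 3.87 ± 0.64. YFP- cells carried the genes of sinusoidal endothelium and leukocytes: the endothelial adhesion molecule Pecam1 was lower in YFP+ by -5.66 ± 0.44 and the pan-leukocyte phosphatase Ptprc by -5.35 ± 0.65. In all, 4373 of 23185 genes passed the threshold, 2412 higher and 1961 lower in YFP+. The fit takes a common spread per gene for all groups. For genes that vary more in YFP-, such as Sox9, the SE and p-values of this contrast are therefore too small.

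Of 31 measured genes of the biliary epithelium list, 29 were higher in untreated YFP+ cells and 1 was lower (30 and 1 when adjusted over the list alone), with a median of 4.27. They included the RNA-binding protein Bicc1 (4.94 ± 1.19), the fibrocystin gene Pkhd1 (4.77 ± 0.84), the membrane glycoprotein Prom1 (4.41 ± 0.76) and the adhesion molecule Epcam (3.75 ± 0.90). Cd24a, at 2.80 ± 0.86, had an adjusted p of 0.0516. The 1 lower member, named after its value was seen, was Aqp1, a water channel of both bile duct and endothelial cells (-4.42; adjusted p = 0.000266). Large rises outside the list were those of Spink4 (5.39 ± 0.83, and 3.66 without UTR replicate 2), a secreted protease inhibitor whose YFP- mean of 4.25 is near the floor, Sorbs2 (5.33 ± 1.06), an adaptor of the actin skeleton, Dsg2 (5.32 ± 1.12), a desmosomal cadherin, Prr15l (5.24 ± 0.87) and Mmp7 (5.23 ± 1.28), an epithelial metalloproteinase.

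Genes of neighbouring programmes were also higher in untreated YFP+ cells. In the primary cilium and cyst list 8 of 14 were higher and 0 lower (9 and 0 adjusted over the list alone), including Bbs1 (2.12 ± 0.24). Among YAP targets 10 of 17 were higher and 1 lower (11 and 1 alone), led by Ccn1 (4.08 ± 0.49) and Ankrd1 (3.75 ± 0.68). The extracellular matrix list had 13 of 23 higher and 2 lower (14 and 2 alone), with the integrin Itga3 at 4.61 ± 0.86 and the growth factors Tgfb2 at 3.46 ± 0.65 and Tgfb1 at -3.13 ± 0.33. In the Wnt list 8 of 18 were higher and 0 lower (8 and 0 alone), among them Wnt4 (2.50 ± 0.30) and the R-spondin receptor Lgr4 (2.46 ± 0.37). Cholesterol and lipid synthesis had 11 of 20 higher and 0 lower (17 and 1 alone), with Scd2 (2.36 ± 0.28) and the squalene epoxidase Sqle (2.24 ± 0.30). NRF2 and heme metabolism had 6 of 20 higher and 0 lower (6 and 1 alone). The progenitor list had 6 of 19 higher and 1 lower (7 and 1 alone): the claudin Cldn6 (4.51 ± 0.39), Sox4 (3.89 ± 0.62) and Klf5 (3.42 ± 0.42) were higher and the receptor Kit was lower (-3.35 ± 0.58). The stem and progenitor markers Lgr5 (-0.06 ± 0.11), Foxl1 (0.33 ± 0.17) and Afp (-0.30 ± 0.21) did not pass. Camera placed these 7 lists and the biliary list higher than other genes (adjusted p from 9.68e-17 for biliary epithelium to 0.0301 for NRF2), and 0 of them passed with an estimated correlation. The call of the progenitor list was lost without YFP- replicate 2 (adjusted p = 0.0517), and that of NRF2 without UTR replicate 2 or YFP- replicate 1 (0.106 at most).

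In the lists of other liver cells, 17 of 18 sinusoidal endothelial genes were lower in untreated YFP+ cells and 0 higher (17 and 0 adjusted over the list alone, median -4.84). Ptprb (-5.85 ± 0.52), the lectin Clec4g (-5.65 ± 0.42) and the scavenger receptor Stab2 (-5.48 ± 0.43) led them. Of 17 macrophage and Kupffer cell genes 10 were lower (14 alone), such as the mannose receptor Mrc1 (-5.88 ± 0.42) and Adgre1, the F4/80 antigen (-4.74 ± 0.87). Neutrophil and monocyte genes were lower in 6 of 12 (6 alone), dendritic cell genes in 3 of 9 (3 alone), lymphocyte genes in 3 of 16 (3 alone) and MHC class II genes in 9 of 11 (10 alone). No member of these 5 leukocyte lists was higher. Large falls were those of Ifi203 (-6.86 ± 0.24) and Ifi204 (-6.73 ± 0.52), interferon-inducible genes, the chemokine Ccl3 (-6.54 ± 0.73), the fatty acid binding protein Fabp4 (-6.50 ± 0.65), Serpina3f (-6.50 ± 0.45) and the nuclease Dnase1l3 (-6.49 ± 0.41). The UTR means of Ifi203, Ifi204 and Serpina3f (3.79, 3.49 and 3.41) lay under the lower quartile of each array, near the floor, so their differences are lower bounds. Cell cycle genes were lower in 12 of 29 (15 alone), including Cdk1 (-2.54 ± 0.43), Top2a (-2.44 ± 0.61) and the proliferation antigen Mki67 (-1.52 ± 0.38). Interferon response genes were lower in 4 of 18 (10 alone), mesenchymal transition genes in 6 of 13 with 1 higher (6 and 1 alone), and unfolded protein response genes in 3 of 19 (3 alone). Camera placed these 10 lists lower (adjusted p from 2.67e-37 for sinusoidal endothelium to 0.0182 for lymphocytes), and 0 of them passed with an estimated correlation. YFP- replicate 2 carried much of 3 of these lists: without it the mean went from -2.45 to -0.82 for lymphocyte genes, whose call was lost (adjusted p = 0.0868), from -1.86 to -1.07 for dendritic cell genes and from -2.63 to -1.58 for neutrophil and monocyte genes. The mesenchymal call was lost without YFP- replicate 1, and the unfolded protein response call without YFP- replicate 1 or 2.

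Hepatocyte genes did not separate untreated YFP+ from YFP- cells as a list (4 higher and 1 lower of 25, over all genes and over the list alone, median -0.12, mean -0.17, test direction up, adjusted p = 0.414). The thyroxine carrier Ttr (1.52 ± 0.13) and the nuclear receptor Hnf4a (2.45 ± 0.37) were higher. The cytochrome Cyp2e1 was lower (-2.83 ± 0.84, a call lost without any 1 of 9 arrays, and -1.80 without YFP- replicate 1). Albumin, Alb, differed by 0.79 ± 0.41 (adjusted p = 0.22, limma). Some hepatocyte genes were bright in untreated YFP+ cells, with means of 12.40 for Alb and 12.95 for Ttr against 10.56 for Krt19. Their YFP- means were 11.6 and 11.42. Of the 25 list genes, 12 were dim in untreated YFP+ cells. The source of the bright hepatocyte transcripts was not tested. The remaining lists did not pass: stellate cell and fibroblast (2 higher, 1 lower of 18, also alone; adjusted p = 0.0884), inflammatory cytokines (2 higher, 4 lower of 23; 2 and 5 alone; 0.0696), Notch (2 higher, 5 lower of 18; 5 and 5 alone; 0.176), immediate early (0 higher, 3 lower of 19, also alone, adjusted p = 0.202), p53 (1 higher, 4 lower of 12; 2 and 6 alone; 0.155) and erythroid and platelet genes (0 higher, 1 lower of 7, also alone, adjusted p = 0.155). With a correlation estimated from the data, 0 of the 18 called lists passed (adjusted p = 0.229 to 0.452 with an estimated correlation), while fry called 20. The count of genes was 2306 without UTR replicate 2, 2432 without UTR replicate 1, and 931 (529 higher, 402 lower) in a fit of these 5 arrays alone. Of the 46 called genes named here, 11 lost their call without UTR replicate 1 and 8 without UTR replicate 2.

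**Figure D1:**
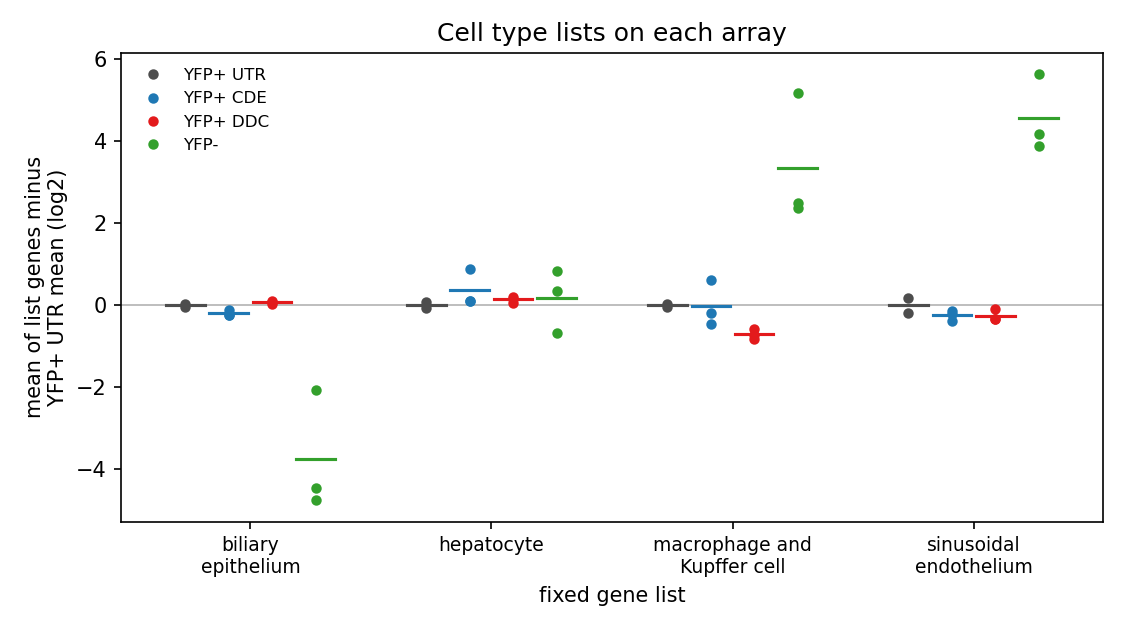
Mean of the genes of 4 fixed lists on each of the 11 arrays, minus the mean of the YFP+ UTR arrays (y axis, log2, where points are arrays, short lines are group means, colours are the 4 groups). The biliary list lay at -2.08, -4.45 and -4.76 on the 3 YFP- arrays, and the hepatocyte list reached 0.89 on CDE replicate 2.

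All YFP+ cells together, whatever the diet, were set against YFP- cells. All YFP- arrays came from untreated mice, so for CDE and DDC this contrast mixes the label with the diet. The contrast called 7083 genes, 3777 higher and 3306 lower in YFP+. The limit of a common spread on SE and p-values holds here too. Epithelial genes led it: Mmp7 (5.57 ± 0.96), Sorbs2 (5.23), Sox9 (5.22), Dsg2 (5.21), Prr15l (5.20 ± 0.65) and Bicc1 (4.92 ± 0.89). Large falls, of which those of Ifi203, Ifi204 and Serpina3f are lower bounds for the same reason, were in Ifi203 (-6.94), Dnase1l3 (-6.70), Serpina3f (-6.61), Fabp4 (-6.60), Ifi204 (-6.51) and the endothelial lectin Clec4g (-6.36). Pecam1 was lower by -5.76, Ptprc by -5.26 ± 0.48 and Adgre1 by -4.78 ± 0.65. The chemokine Cxcl5 was higher in YFP+ cells (3.86 ± 0.32) and its relative Cxcl2 lower (-3.03 ± 0.41), although Cxcl2 on the DDC arrays (9.75 to 10.81) overlapped with YFP- (9.95 to 11.90).

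Biliary genes were higher in 30 of 31 and lower in 1 (30 and 1 adjusted over the list alone, median 4.18), sinusoidal endothelial genes were lower in 17 of 18 (17 alone, median -4.91) and macrophage genes in 15 of 17 (17 alone, median -3.63). Camera called 18 lists, 8 higher and 10 lower in YFP+. With an estimated correlation 0 passed (adjusted p = 0.257 for biliary, endothelial and macrophage genes with an estimated correlation), and fry called 20. Hepatocyte genes were split, 6 higher and 2 lower of 25 (8 and 8 alone), with a median of -0.03 and a mean near 0 against a test direction of up (adjusted p = 0.291). With array weights the contrast called 4534 genes, 2303 higher and 2231 lower.

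The CDE diet was compared with no treatment to show how the biliary lineage responds to this injury. The common spread of the 11-array fit includes the YFP- arrays. For genes that vary more in YFP-, its SE and p-values for comparisons among YFP+ groups are therefore too large. No single gene passed with limma in 11 arrays (0 of 23185; lowest adjusted p = 0.344; 598 at an unadjusted p under 0.05, against 1159 by chance) or in the 8 YFP+ arrays (0 genes; lowest adjusted p = 0.0558; 1492 unadjusted). The lowest p in both fits belonged to Rnu7, the U7 small nuclear RNA of histone mRNA processing, named after its value was seen: 5.92 ± 0.25 (SD, n = 3) in CDE against 3.96 ± 0.19 (SD, n = 2) in UTR, a difference of 1.96 ± 0.17 in 8 arrays, which is a lower bound since the UTR mean is near the floor. Differences over 2 log2 units included those of the iron hormone hepcidin, Hamp (5.73 ± 0.90, adjusted p = 0.264 in 8 arrays), its paralog Hamp2 (at least 3.35 ± 0.56, with a UTR mean of 3.63 near the floor; 0.315) and the BMP-responsive inhibitors Id1 (2.22 ± 0.29; 0.18) and Id3 (2.08 ± 0.26; 0.18), all chosen after their values were seen. The biliary list member Dmbt1 (-3.12 ± 1.12; 0.7) read 7.81 and 11.98 on the 2 UTR arrays.

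Cholesterol and lipid synthesis was the 1 list called in CDE, lower by camera (adjusted p = 0.0284; 15 of 20 members negative, median -0.22, 0 past the threshold over all genes or over the list alone). Its call was lost with an estimated correlation (adjusted p = 0.974 with an estimated correlation) and fry called 0 lists. Among its members the synthase Hmgcs1 was at -0.64 ± 0.46. Biliary identity genes differed little, with Krt19 at -0.31 ± 0.14, Krt7 at -0.36 ± 0.17, Epcam at 0.12 ± 0.10 and Sox9 at -0.02 ± 0.12 (SE of 8 arrays). Hepatocyte genes were positive in 21 of 25 (median 0.26, camera adjusted p = 0.0792), and 0 members passed over all genes or over the list alone. On CDE replicate 2 the mean of this list lay 0.89 above untreated, with Fgb, the fibrinogen beta chain, at 11.22 and Apoc3, an apolipoprotein, at 7.80, against list means of 0.10 and 0.12 on replicates 1 and 3. Fgb also read 9.73 to 10.81 on the DDC arrays, where the median of the hepatocyte list lay at 0.02, -0.10 and -0.02 from untreated. Fgb was thus high there without a rise of the list as a whole, so its level alone was not taken as a mark of hepatocyte RNA. Cell cycle genes had a median of 0.05 (19 of 29 positive, camera adjusted p = 0.255, 0 past the threshold, also alone) and Mki67 differed by 0.02 ± 0.32 (SE of 8 arrays). In the 8 arrays camera called 5 lists, hepatocyte and stellate cell genes higher and biliary, endothelial and cholesterol genes lower, and 0 of these held with an estimated correlation (adjusted p = 0.592 with an estimated correlation).

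Leaving out UTR replicate 1 raised the count for CDE from 0 to 17 genes in 11 arrays and to 46 in 8. Without CDE replicate 2 or without UTR replicate 1 the 11-array fit called 0 lists, and the cholesterol call was lost without UTR replicate 2 too. In 8 arrays the mean of the hepatocyte list went from 0.37 to 0.11 without CDE replicate 2 and that of the endothelial list from -0.25 to -0.06 without UTR replicate 2, which ended both calls. The hepatocyte call was also lost without UTR replicate 1, and the cholesterol call in 8 arrays without CDE replicate 2 or either UTR replicate. The stellate cell call was lost without any 1 of 5 arrays, and the biliary call without CDE replicate 2 or UTR replicate 1.

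DDC was compared with no treatment for the same question in the other injury. Single genes did not pass in the 11 arrays (0 of 23185 with limma; lowest adjusted p = 0.165; 1082 at an unadjusted p under 0.05), while the 8 YFP+ arrays called 37 genes, 22 higher and 15 lower (2417 unadjusted), of which 0 stayed past the threshold with the replicate number as a block. In those 8 arrays the neutrophil chemokine Cxcl2 rose by 3.73 ± 0.36 (adjusted p = 0.0209), from 6.61 ± 0.71 (SD, n = 2) to 10.34 ± 0.54 (SD, n = 3), and in 11 arrays its adjusted p was 0.228. The haptoglobin gene Hp, an acute phase product, rose by 3.30 ± 0.31, Cxcl3 by 3.07 ± 0.38 and Cxcl1 by 1.62 ± 0.21 (adjusted p = 0.0209, 0.0308 and 0.0325).

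Other genes that rose on DDC in the 8 arrays were the carboxypeptidase Cpe (2.82 ± 0.30), the intestinal cadherin Cdh17 (2.69 ± 0.24), the peptidoglycan recognition gene Pglyrp4 (2.42 ± 0.30), the metalloproteinase inhibitor Timp1 (2.02 ± 0.15, adjusted p = 0.0181), the G-protein regulator Rgs5 (1.68 ± 0.20), the hyaluronan receptor Cd44 (1.20 ± 0.13) and the laminin chain Lamb3 (1.11 ± 0.15). Genes that fell were the antiprotease genes Serpina1d (-2.88 ± 0.31) and Serpina1e (-1.54 ± 0.18), the imprinted transcript Peg3os (-1.88 ± 0.16), the monooxygenase Fmo2 (-1.72 ± 0.21), the clock transcription factor Npas2 (-1.61 ± 0.20), the membrane glycoprotein Emb (-1.46 ± 0.18) and the interferon-induced Ifit2 (-1.27 ± 0.16). The Serpina1 genes are close paralogs, and hybridisation between them was not tested. The lower means of Cxcl3, Cdh17, Pglyrp4 and Serpina1d (4.10 to 4.21) lay near the floor, so their differences are lower bounds. Biliary markers did not pass in either fit, with Krt19 at -0.08 ± 0.14, Epcam at 0.17 ± 0.10 and Sox9 at -0.06 ± 0.12 (SE of 8 arrays), and the biliary list as a whole had a median of 0.13 (adjusted p = 0.635; 0 members past the threshold, also alone).

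Camera called 8 lists on DDC in 11 arrays. All 29 cell cycle genes were positive (median 0.60, adjusted p = 6.44e-20, and 0.216 with an estimated correlation); 0 passed over all genes and 5 rose when adjusted over the list alone. The largest were the topoisomerase Top2a (1.77 ± 0.61) and the kinase Cdk1 (1.67 ± 0.43), and Mki67 differed by 1.29 ± 0.38. Inflammatory cytokines and NF-kB genes were positive in 21 of 23 (median 0.64, adjusted p = 1.81e-09, and 0.216 with an estimated correlation), with 0 past over all genes and 2 alone; the monocyte chemokine Ccl2 was at 1.84 ± 0.73, and at 0.47 without UTR replicate 2. Matrix and fibrogenic genes were positive in 18 of 23 (median 0.33, 0.000377, and 0.879 with an estimated correlation, 0 and 3 alone). The immediate early list (16 of 19 positive, median 0.34, 0.0283, and 0.971 with an estimated correlation) and the p53 list (10 of 12, median 0.31, 0.0185, and 0.216 with an estimated correlation) had 0 members past either way. On the negative side stood all 18 interferon response genes (median -0.37, adjusted p = 1.97e-06, and 0.653 with an estimated correlation, 0 and 1 alone), 18 of 20 cholesterol and lipid genes (median -0.40, 1.56e-09, and 0.216 with an estimated correlation, 0 and 0 alone), such as Hmgcs1 (-1.24 ± 0.46) and the sterol sensor Insig1 (-1.08 ± 0.38), and 16 of 17 macrophage genes (median -0.59, 0.0025, and 0.971 with an estimated correlation, 0 and 0 alone), such as Vsig4 (-1.97 ± 0.92). Fry called 0 lists in 11 arrays and 1, cholesterol and lipid synthesis, in 8 (adjusted p = 0.0498). Without UTR replicate 2 the means of the interferon and matrix lists went from -0.47 to -0.19 and from 0.40 to 0.21, which ended both calls in 11 arrays, and that of the inflammatory list from 0.80 to 0.48, still called. Without UTR replicate 1 the mean of the immediate early list went from 0.35 to 0.16. That call was also lost without DDC replicate 1 or 2, the p53 call without DDC replicate 2 or UTR replicate 2, and the macrophage call without UTR replicate 1.

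Without DDC replicate 2 the 8-array fit called 0 genes, and without UTR replicate 1 it called 103. All 37 genes had the same sign under each left-out array, which their selection on these arrays largely assures. Of them, 0 stayed past the threshold without DDC replicate 2 or without UTR replicate 2.

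**Figure D2:**
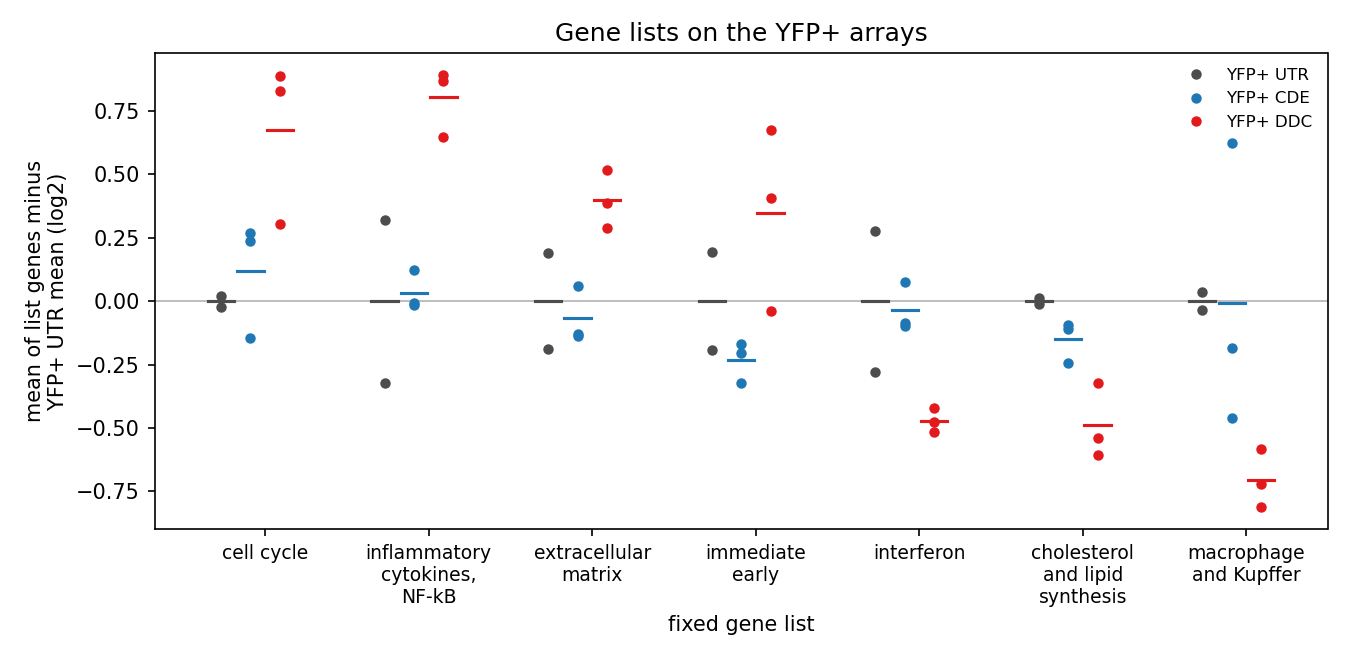
Mean of the genes of 7 fixed lists on each of the 8 YFP+ arrays, minus the mean of the UTR arrays (y axis, log2, where points are arrays, short lines are group means, colours are the 3 groups). The cell cycle list lay at 0.31, 0.89 and 0.83 on the DDC arrays and at -0.15, 0.24 and 0.27 on the CDE arrays, and the immediate early list at 0.68, 0.41 and -0.04 on the DDC arrays.

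DDC and CDE were compared directly to show where the 2 injuries differ. The duration of the CDE diet is not given in the sources used here, so an effect of diet cannot be told apart from one of exposure time. In the 11 arrays 1 gene passed, Rnu7, lower in DDC by -2.50 ± 0.23 (adjusted p = 0.0326, limma), with 1792 genes at an unadjusted p under 0.05. Its means were 3.42 ± 0.17, near the floor, and 5.92 ± 0.25 (SD, n = 3 each), so the difference is a lower bound. The call of Rnu7 was lost without any 1 of the 8 YFP+ arrays (adjusted p = 0.196 at most) and with the replicate block, and the gene is too dim for the filter on dim genes. In the 8 arrays its adjusted p was 0.0017. These arrays called 269 genes, 97 higher and 172 lower in DDC, of which 99 changed at least 2-fold and 60 stayed past the threshold with the replicate block. A fit of the 6 arrays of these groups alone, planned from the start, called 211 (85 higher, 126 lower), and array weights over all 11 arrays called 337 (105 higher, 232 lower).

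In the 8 arrays large rises in DDC against CDE were those of Cxcl2 (3.16 ± 0.32, adjusted p = 0.0107), Cxcl3 (3.04 ± 0.34), the antiprotease Slpi (2.79 ± 0.50), the calcium-binding protein S100b (2.41 ± 0.27), the epithelial chemokine Cxcl5 (2.36 ± 0.31) and Pglyrp4 (2.29 ± 0.27). Their adjusted p-values in 11 arrays were 0.063 to 0.291. Large falls were those of Hamp (-5.68 ± 0.81, adjusted p = 0.0247), the corticosteroid carrier Serpina6 (-3.46 ± 0.51), Hamp2 (-3.10 ± 0.50), Serpina1d (-2.52 ± 0.28), the carboxylesterase Ces1c (-2.27 ± 0.35) and the complement component C9 (-2.24 ± 0.12, adjusted p = 0.00167). The differences of Cxcl3, Hamp2 and Serpina1d are lower bounds, with lower means of 4.12, 3.88 and 4.16. Hamp stood at 5.21 ± 1.34 in DDC and 10.89 ± 1.42 in CDE (SD, n = 3 each). Timp1 (1.77 ± 0.14), Hp (1.88 ± 0.28), Cdh17 (2.16 ± 0.21), Lamb3 (1.41 ± 0.14) and Cd44 (0.75 ± 0.11) were also higher in DDC, and the oncofetal glypican Gpc3 (-1.67 ± 0.18), Id1 (-1.75 ± 0.26), Npas2 (-1.58 ± 0.18), Fmo2 (-1.46 ± 0.19), Emb (-1.54 ± 0.16) and Alb (-0.73 ± 0.09) lower (adjusted p = 0.00716 to 0.0293). The hepatocyte list, which holds Alb, was lower in DDC too (median -0.27 in 11 arrays). A difference in hepatocyte RNA between the diets was not tested for the genes that fell.

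Camera called 9 lists between the diets in 11 arrays, 4 higher and 5 lower in DDC, and 0 with an estimated correlation. In 8 arrays it called 10, 5 higher and 5 lower, and 0 with an estimated correlation. The list added there was biliary epithelium, higher in DDC (mean 0.27), a call kept under each left-out array (camera adjusted p = 0.00636 at most). Inflammatory and NF-kB genes were positive in 20 of 23 (median 0.53, adjusted p = 4.21e-09, and 0.269 with an estimated correlation); 0 rose over all genes and 3 over the list alone in 11 arrays, and 5 and 14 in 8 arrays, tumour necrosis factor, Tnf (1.40 ± 0.25), among them. All 29 cell cycle genes were positive (median 0.54, 2.82e-12, and 0.638 with an estimated correlation), with 0 past either way in 11 arrays and 0 and 13 in 8. Matrix genes were positive in 17 of 23 (median 0.36, 7.59e-05, and 0.638 with an estimated correlation, 0 and 2 alone), with the laminin Lama5 at 0.88 ± 0.15 in 8 arrays. Immediate early genes were positive in 18 of 19 (median 0.55, 6.85e-05, and 0.638 with an estimated correlation, 0 past either way), Ier3 at 0.83 ± 0.14.

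Lower in DDC than in CDE by camera were all 18 interferon genes (median -0.44, adjusted p = 6.85e-05, and 0.638 with an estimated correlation, 0 past either way), all 17 macrophage genes (median -0.54, 0.00196, and 0.75 with an estimated correlation, 0 past either way), 17 of 20 cholesterol genes (median -0.35, 0.00185, and 0.638 with an estimated correlation, 0 past either way), 21 of 25 hepatocyte genes (median -0.27, 0.028, and 0.84 with an estimated correlation, 0 past either way) and 8 of 11 MHC class II genes (median -0.17, 0.0461, and 0.75 with an estimated correlation, 0 past, 1 fell alone). Ifit2 fell by 0.86 and the sterol desaturase Sc5d by 0.58 in 8 arrays (adjusted p = 0.0396 and 0.0404). Leaving out 1 array ended the hepatocyte call (CDE replicate 2, DDC replicate 2 or 3, or YFP- replicate 2), the macrophage call (CDE replicate 3) and the MHC class II call (any 1 of 8 arrays). The mean of the hepatocyte list went from -0.22 to 0.04 without CDE replicate 2, and that of the macrophage list from -0.70 to -0.38 without CDE replicate 3. Beside the macrophage list, CDE replicate 3 lay 0.62 above untreated in the mean of these genes, and CDE replicates 1 and 2 lay at -0.46 and -0.18. Macrophage and MHC class II genes mark YFP- cells, and RNA from such cells was not tested as the source of these differences. Beside the hepatocyte list, CDE replicate 2 lay at 0.89, and this list held Hp, which moved the other way. Fry called 0 lists in 11 arrays and 1 in 8, liver progenitor and ductular reaction (adjusted p = 0.00781), in which Cd44 rose and Gpc3 fell.

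The 8-array count ran from 16 without CDE replicate 3 to 211 without UTR replicate 1. All 269 genes kept their sign under each left-out array, which their selection on these arrays largely assures, and 16 to 169 of them stayed past the threshold. Of the genes named for this fit, C9, Lamb3, Rnu7 and Timp1 passed under each left-out array.

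**Figure D3:**
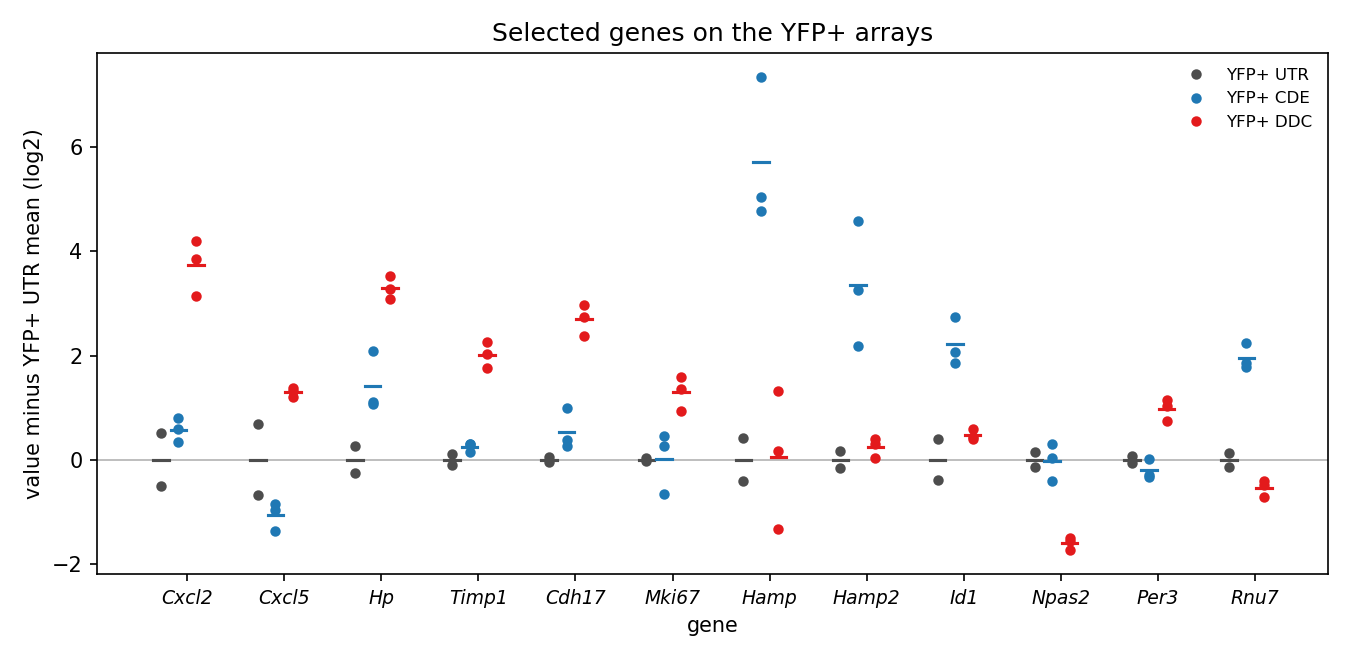
Values of 12 genes on each of the 8 YFP+ arrays, minus the mean of the UTR arrays (y axis, log2, where points are arrays, short lines are group means, colours are the 3 groups). Hamp and Rnu7 lay highest on the CDE arrays (means of 5.73 and 1.96), Cxcl2 and Hp on the DDC arrays (3.73 and 3.30).

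The effects of the diets were also set against each other, both relative to the same 2 UTR arrays. The log2 differences of CDE and DDC correlated across 23185 genes with r = 0.362, where genes are not independent replicates. Unchanged groups simulated against the same UTR arrays gave 0.601 on average (0.576 to 0.626). The covariance was 0.0238 against 0.0251 simulated, a difference of -0.00125. At an unadjusted p under 0.05 in 8 arrays, 198 genes were higher in both (39 for independent lists) and 195 lower in both (38), and the 393 together compared with 396 simulated. Adjusted calls could not be shared, since limma called 0 genes for CDE against UTR in both fits (598 and 1492 unadjusted). The controls were not split, since each part would hold 1 array. The overlap was no larger than shared controls alone gave in the simulation, and all of it may come from them.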

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

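The tests of RNA from other cells, of cell isolation, of hepatocyte RNA and of a BMP response, and the splits and calls of the 8 YFP+ arrays, were chosen after the results were seen. The splits of the 11-array fit were planned. What draws attention here is a difference between the YFP+ samples of DDC and CDE, tested as DDC minus CDE. In 11 arrays it was past the threshold for Rnu7 (-2.50), and in 8 arrays also for Hamp (-5.68), Serpina6 (-3.46), Hamp2 (-3.10), Serpina1d (-2.52), Ces1c (-2.27), C9 (-2.24), Pglyrp4 (2.29), Cxcl5 (2.36), S100b (2.41), Slpi (2.79), Cxcl3 (3.04) and Cxcl2 (3.16). The differences of Rnu7, Hamp2, Serpina1d and Cxcl3 are lower bounds, since their lower means are near the floor. In 11 arrays the 9 lists that differed by camera, 0 of which passed with an estimated correlation or with fry, had medians of -0.27 (hepatocyte), -0.54 (macrophage and Kupffer cell), 0.54 (cell cycle), 0.53 (inflammatory cytokines and NF-kB), 0.36 (extracellular matrix), -0.44 (interferon response), -0.17 (MHC class II), -0.35 (cholesterol and lipid synthesis) and 0.55 (immediate early). The 6 arrays of these groups allow 10 splits, too few for a share under 0.05: 1 split, the real one, gave as many genes as the real split in each fit, with 1 gene in 11 arrays and 269 in 8, against a highest other split of 0 in both. For the lists the real split gave 9 in 11 arrays and 10 in 8, against a highest other of 6 and 8. Among the lists, macrophage and MHC class II genes were lower in YFP+ than in YFP- cells. A difference in RNA from YFP- cells was not tested as the source of their lower values in DDC. Leaving out 1 array ended the 11-array calls of Rnu7 (each of the 8 YFP+ arrays), of the macrophage list (CDE replicate 3; mean from -0.70 to -0.38), of MHC class II genes (8 of the 11 arrays) and of the hepatocyte list, whose mean went from -0.22 to 0.04 without CDE replicate 2.

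Camera placed inflammatory genes higher in DDC than in CDE, with 20 of 23 members positive, but the list did not pass with an estimated correlation (adjusted p = 0.269 in 11 arrays) or with fry, and members passed over all genes in the 8 arrays only (5, with Cxcl2 at 3.16). RNA from leukocytes or other YFP- cells, which the sort on YFP should remove, was tested on 44 marker genes. They came from the macrophage, neutrophil, dendritic cell, lymphocyte and endothelial lists and were lower in YFP+ than in YFP- cells. Their median difference was -0.132 and 13 were higher in DDC, which argues against endothelial and macrophage RNA, which most of the 44 mark. The endothelial lectin Clec4g stood at 4.80, 6.04 and 4.94 on the DDC arrays against 11.87 to 12.82 on the YFP- arrays. For neutrophil and lymphocyte RNA the test decides less, since fewer of the 44 mark these cells and the DDC arrays took part in choosing them. A response to tissue digestion and sorting stays open, since 18 of 19 immediate early genes were higher in DDC; their mean lay at 0.68, 0.41 and -0.04 on the DDC arrays, where the inflammatory list lay at 0.89, 0.87 and 0.65. An effect of the DDC diet on the biliary lineage also stays open and was not tested apart from isolation. Candidate explanations are therefore isolation, the diet or both, with RNA from neutrophils or lymphocytes not excluded.

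Hamp, Hamp2, Id1 and Id3 had higher means in CDE than in UTR (by 5.73, at least 3.35, 2.22 and 2.08), with adjusted p-values of 0.18 to 0.315 in the 8 arrays. Hepcidin is a hepatocyte product, so hepatocyte RNA, which slow centrifugation and the YFP gate should reduce, was tested on 12 hepatocyte list genes that are dim in UTR: on replicates 1 and 3 the higher of the medians was 0.077, with 5 of 12 above both UTR arrays on each, which argues against it there, where Hamp still read 10.21 and 9.93 against 4.75 and 5.57 in UTR. On replicate 2 the median was 0.498, with 10 of 12 above both UTR arrays and Apoc3 at 7.80, so hepatocyte RNA and expression by the sorted cells cannot be told apart for that array, because the value sits at the bound set for the test. A response to BMP signalling cannot be told apart from another effect of the CDE diet, which was not tested: 6 of 7 other BMP and SMAD response genes (Id2, Id4, Smad6, Smad7, Smad9, Atoh8 and Bambi) had positive differences, but they were chosen after their values were seen and none passed (adjusted p = 0.655 to 0.993 in 8 arrays).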

How the results depend on the processing

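The fit of the 8 YFP+ arrays, with its alternatives, was chosen after the data were seen; all other alternatives and the splits of the 11-array fits were planned. No named gene that passed the threshold in the 11-array result or under an alternative to it changed sign between them. For named genes that passed in neither, signs were not compared. Against the 11-array result, named genes lost their call in 55 of 963 values for UTR against YFP- (7 gained one), 0 of 303 for YFP+ against YFP- and 9 of 970 for DDC against CDE (125 gained). For CDE and DDC against UTR 2 of 672 and 32 of 734 gained one. Quantile normalization and all features moved no count of genes by over 1.5 times, and median centring and the trend moved only those given below. The fit of the 8 YFP+ arrays has the same log2 differences as the 11-array fit. It differs only in its estimate of the spread and its degrees of freedom. Where another value below differs from the 11-array result, the cause was not tested unless given.

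For UTR against YFP- (4373 genes, 18 lists) a 2-fold threshold left 2798 genes and an estimated correlation left 0 lists. The 5 arrays alone gave 931 genes, with fewer samples and a spread that leaves out the less variable CDE and DDC arrays. For YFP+ against YFP- (7083 genes, 18 lists) array weights gave 4534 genes, a 2-fold threshold 3235 and an estimated correlation 0 lists. Other splits of the 11 arrays into 8 and 3 (100 of 165 drawn) did not reach the 7544 genes of the real split in a 2-group fit: 1 split, the real one, gave as many, and the highest other gave 8. For lists 3 of the 100, the real one among them, gave the real 18 or more, the highest other also 18. Every other split leaves at least 1 YFP- array in the larger group, which widens the spread within groups. This favours low counts of genes, so the splits alone cannot exclude chance for that count. The count of lists does not set the real split apart, since other splits reached it.

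For CDE against UTR (0 genes, 598 unadjusted; 1 list) array weights gave 1 gene; lists called were 4 without dim genes, 3 with quantile normalization (1 higher, 2 lower, against 0 and 1), 2 with median centring (1 and 1), 3 with array weights, 3 in the 5 arrays alone, 5 in 8 arrays, and 0 with an estimated correlation or fry. For DDC against UTR (0 genes, 1082 unadjusted; 8 lists) array weights gave 11 genes and the 8 arrays 37, and an estimated correlation and fry left 0 lists. For DDC against CDE (1 gene, 9 lists) the trend gave 3 genes, the dim filter 0, median centring 6 (3 higher, 3 lower, against 0 and 1), array weights 337, the 6 arrays alone 211 and the 8 arrays 269, and an estimated correlation and fry left 0 lists.

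Within the 8 arrays, CDE against UTR (0 genes, 1492 unadjusted; 5 lists) gave 1 gene with the trend, median centring or array weights, and 0 lists with an estimated correlation or fry. DDC against UTR (10 lists) kept 0 lists with an estimated correlation and 1 with fry. DDC against CDE gave 99 genes at 2-fold, and of its 10 lists 0 held with an estimated correlation or fry, which called 1 other list. Quantile normalization moved the share of higher calls there from 36.1% (of 269) to 47.4% (of 272). The median of all genes stayed between -0.049 and 0.044 under every scaling.

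Leaving out 1 array gave 2306 to 5817 genes and 16 to 19 lists for UTR against YFP-, and 5887 to 7797 and 16 to 20 for YFP+ against YFP-. In 11 arrays it gave 0 to 17 genes and 0 to 4 lists for CDE, 0 to 14 and 5 to 9 for DDC, and 0 to 56 (56 without YFP- replicate 1) and 7 to 12 for DDC against CDE. In 8 arrays the ranges were 0 to 46 and 1 to 9, 0 to 103 and 9 to 11, and 16 to 211 and 8 to 12. The correlation of the diets' effects ran from 0.285 to 0.596 and their shared calls from 0 to 12, the highest of each without UTR replicate 1. A lone UTR array was then assumed to vary like the other groups.

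The replicate numbers did not pair the arrays: deviations of the 15 same-numbered pairs correlated by -0.072 to 0.131, with 1 over 0.1. With the replicate block, CDE against UTR had 0 lists, DDC against CDE 0 genes in 11 arrays and 61 (24 higher, 37 lower) in 8, and DDC against UTR 0 genes in 8. It moved no other count by over 1.5 times. Each symbol had 1 feature, so the mean of features changed nothing and has no value, and for YFP+ against YFP- the groups compared are all arrays. Signal over background was not used here.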

Other observations

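All genes named in this part, and the test on clock genes, were chosen after their values were seen. Besides Rnu7, 2 small noncoding RNAs of the nucleus were lower in DDC than in CDE in the 8 arrays: Snord13, a nucleolar guide RNA of ribosome assembly, differed by -3.11 ± 0.57 (adjusted p = 0.0476, limma on 8 arrays; 0.124 in 11) and Rnu3a, the U3 RNA of ribosomal RNA processing, by -2.16 ± 0.32 (0.0272; 0.172 in 11). How well the labelling captures such short RNAs is not given in the sources used here.

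The 2 untreated YFP+ arrays differed widely in 3 genes of secreted proteins. Replicate 2 read 11.98 for Dmbt1, a mucosal scavenger glycoprotein, 11.37 for Spink4 and 9.14 for the lactoferrin gene Ltf, against 7.81, 7.91 and 4.52 on replicate 1. On the CDE arrays Dmbt1 lay at 6.93, 5.77 and 7.64 and on the DDC arrays at 9.51, 7.69 and 8.32. This spread between 2 arrays was not tested.

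Circadian clock genes differed between DDC and CDE in the 8 arrays. The activators Arntl (-1.86 ± 0.29) and Npas2 (-1.58 ± 0.18) were lower in DDC, and the clock-controlled genes Per3 (1.18 ± 0.14), Dbp (1.18 ± 0.17), Tef (1.22 ± 0.20), Bhlhe41 (1.45 ± 0.18) and Per2 (0.86 ± 0.14) higher, with adjusted p-values of 0.014 to 0.0372. A shift of phase predicts opposite signs for activators and their targets: 13 of 16 clock genes had that sign for DDC minus CDE, 14 for DDC minus UTR and 7 for CDE minus UTR, but the set holds the genes that drew attention, so these counts do not test a shift. A different time of day at collection may account for this, but the labels give no such time, so it cannot be told apart from an effect of the diet on the clock or on feeding, which was not tested.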
